A study of Mus musculus with 22 samples.

How the data were processed

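RNA of mouse macrophages from atherosclerotic aortas was measured by RNA sequencing in 22 libraries of 5 groups. The design text of the series describes Ldlr-null, CD45.2 donor mice that were diabetic and ate a Western diet. Their aortas were either taken without transplant or transplanted into chow-fed diabetic CD45.1 hosts, which were wild type (WT) or lacked Ager, the gene of the receptor RAGE. Macrophages of host origin (recipient) and of donor origin (graft) were profiled apart. How the cells were sorted is not given in the sources used here. The groups and replicate numbers were taken from the sample titles: untransplanted donor (4 libraries), WT recipient (4), donor into WT (4), Ager-null recipient (6) and donor into Ager-null (4). The labels do not say that the libraries come from separate mice, so p-values measure the spread between these samples, which may be technical.

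Per the labels' protocols, total RNA was amplified with the NuGEN Ovation RNA-Seq system v2 and adapters were ligated with the Ovation Ultralow DR Multiplex system. Per the submitters' processing notes, the tools were bcl2fastq 1.8.4, Trimmomatic (version not given), Bowtie2 2.1.0, TopHat2 2.0.0 and HTSeq 0.6.1, with the genome build mm10. The notes give neither their roles nor the annotation, the filters or whether counting used strand. The authors deposited 1 table of whole-number read counts per gene symbol for 52459 genes, with no normalization, and all 22 columns matched a sample. No duplicate removal or molecular identifier is stated, so PCR copies may be counted, and intervals and floors given for counts cover counting error only. Without stated stranding, reads of a gene and an antisense or overlapping neighbour cannot be told apart. Counts of near-identical genes are uncertain where reads could be split between copies, which concerns the H2 genes, the Cd209 family, Hba-a1 with Hba-a2, and Hspa1a with Hspa1b.

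Total counts ran from 19.8 to 50 M per library, and 15140 to 22125 genes had a count. A count of 0 was taken to allow up to 3 counts. Mitochondrial ribosomal RNA took from 5.39% (95% Wilson interval 5.38 to 5.4) of the counts, in WT recipient replicate 1, to 32.4% (32.3 to 32.4), in untransplanted donor replicate 2. Of the 231 pairs of libraries none held identical counts, and the smallest chi-square per degree of freedom was 112 over all pairs and 141 within a group, so no library was counted as a copy of another.

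Choices described here were made before the data were examined unless stated otherwise. Genes were kept by edgeR's filterByExpr by group (minimum count 10, minimum total 15), which left 17288 genes. Libraries were scaled by TMM, and all 22 entered 1 model with 5 group means, so that the groups shared 1 estimate of the spread. Genes were tested with edgeR 4.0.16 in R 4.3.3 (robust dispersion, glmQLFit robust, glmQLFTest, two-sided), with Benjamini-Hochberg adjustment over the genes tested, a threshold of 0.05 and no fold minimum. The common dispersion was 1.16, a biological coefficient of variation of 1.08. Log2 fold changes are given ± SE, the SE being the fold change divided by the square root of the test's F value, and group levels are mean CPM ± SD with TMM-scaled library sizes. Sums over a list's genes are CPM without TMM factors.

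The 30 gene lists were interferon-stimulated, interferon-gamma and guanylate-binding, MHC class II, inflammatory cytokine and NF-kB, RAGE ligand and signalling, alternative activation, resident-like macrophage, monocyte-derived, lipid-laden Trem2 macrophage, cholesterol efflux and LXR, cholesterol biosynthesis, glycolysis, oxidative phosphorylation, cell cycle, unfolded protein response, migration and chemokine receptor, efferocytosis, matrix and protease, immediate early, core macrophage, smooth muscle, fibroblast, endothelial, T cell, B cell, NK cell, neutrophil, dendritic cell, adipocyte and erythroid. Each was tested in the same model with camera from limma 3.58.1 (preset correlation 0.01), which sets a list against the other genes, with adjustment over the 30 lists within a comparison. An adjusted p of a list is camera's with the preset correlation unless an estimated correlation or fry is named. Fry asks whether a list's genes move one way on balance and does not set them against other genes. A list score is the mean log2 CPM of its tested members in a library, with a prior count of 2. Some lists share genes, so their tests are not independent.

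Genes named in the text were chosen by rule. They are Ager, Ldlr, Ptprc and Irf7; in each comparison up to 10 higher and 10 lower genes with the smallest p among those past the threshold, with an absolute log2 fold change of at least 1 and a mean CPM of at least 5, leaving out predicted and clone-named genes, or the 3 genes with the smallest p where none passed; and the members with the smallest p of lists that passed or held a called gene, and of the interferon-stimulated, cholesterol and inflammatory lists in any case. The rule allowed up to 4 members per list; the narrowing to 2 was set after values had been seen. Gene positions are from a GRCm38 annotation, the assembly that mm10 names, and 160 of 160 named genes were placed. They show where a gene lies, not where its reads fell.

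Label genes were compared with exact two-sided permutation tests over all splits (scipy 1.17.1). The comparisons of each graft group with the untransplanted donors share 4 control libraries, and the covariance of their fold changes was set beside 20 simulations of unchanged groups and beside splits of the controls into pairs. The alternatives were RLE size factors, DESeq2 1.42.0, limma-voom with sample quality weights, only the groups compared in the fit, no low-count filter, a stricter filter (CPM of 5 in 4 libraries), the replicate number as a block, neighbouring sample numbers as a block, the range of the sample number as a term, and each library left out in turn. Sample numbers in the labels fall in 3 ranges, 27 to 48 (5 libraries), 84 to 138 (10) and 176 to 186 (7). The labels do not say what these numbers mean, and the ranges were treated as possible batches. Fits without the library labelled donor into WT replicate 3 and without 3 fibroblast-transcript-rich graft libraries, and the comparison of origin averaged over hosts, were added after the data were seen. The fit without the 3 graft libraries left only replicate 4 and the library labelled replicate 3 in donor into WT.

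The gene test was tested on simulated counts with 200 genes changed, in 5 simulations per comparison of 16607 to 16730 tested genes for donor into Ager-null against donor into WT and 16641 to 16714 for Ager-null against WT recipients. For Ager-null against WT recipients, 2.09% of genes changed by log2 1 were recovered, 32.5% of those changed by 2 and 66.1% of those changed by 3, with 69.6 calls and 2.8 false calls on average. For donor into Ager-null against donor into WT the shares were 1.49%, 20.6% and 58.8%, with 55.6 calls and 2 false calls. A simulated shift of a list by -0.5 was found in 5 of 5 simulations of each comparison, at an unadjusted camera p under 0.05. The simulated genes were drawn independently of each other. These simulations therefore do not show how the list test does where genes of a list vary together.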

Results

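Macrophages were profiled from aortas that carried diabetic atherosclerosis, either left in the donor or moved into diabetic hosts on chow, a setting in which plaques can regress. The series asks what the host's lack of RAGE, a receptor for glycated proteins and S100 proteins, does to the macrophages that enter the aorta (recipient) and to those that stay in it from the donor (graft). Total counts were 21.7 to 39.5 M in the 4 untransplanted donor libraries, 19.8 to 50 M in the 4 WT recipient, 23.9 to 37.8 M in the 4 donor into WT, 21.4 to 37.5 M in the 6 Ager-null recipient and 22.5 to 36.7 M in the 4 donor into Ager-null libraries. Group levels are mean CPM ± SD over these n, and gene p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

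Ager, which encodes RAGE (GRCm38 chromosome 17, 34597460 to 34600937), was low and uneven between the libraries of a group, at most 6.25 CPM. Its CPM was 2.44, 0.0983, 0.165 and 3.43 in WT recipient replicates 1 to 4. In Ager-null recipient replicates 1 to 6 it was 0.795, 0.229, 0.197, 6.25, 0.597 and 0.166. The means were 1.53 ± 1.67 (SD, n = 4) and 1.37 ± 2.4 (SD, n = 6), with an exact two-sided permutation p = 1. Leaving out WT recipient replicate 1 or 4 (p = 0.857 each) or Ager-null recipient replicate 2, 3 or 6 (p = 0.889 each) by the same exact permutation test turned the difference around. In the donor-derived libraries, which carry Ager, it was 0, 0, 0.238 and 0 in untransplanted donor, 0, 0.309, 5.34 and 0 in donor into WT, and 5.85, 0, 1.44 and 0 in donor into Ager-null. A count of 0, found in 7 libraries, allows up to 0.0745 to 0.144 CPM. The Ager counts therefore do not separate the host genotypes, which rest on the labels, and the highest value came from the library labelled Ager-null recipient replicate 4. Counts were summed per gene, and which part of Ager the null allele lacks is not given in the sources used here.

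Ldlr, the LDL receptor gene (chromosome 9, 21723576 to 21749919), is disrupted in the donors and intact in the hosts. Its CPM was 9.84, 37.9, 0.333 and 4.09 in untransplanted donor, 14.2, 11.5, 3.73 and 3.37 in donor into Ager-null, and 16, 3.84, 74.6 and 7.16 in donor into WT. In the recipients it was 77.2, 62.4, 78 and 55.1 (WT) and 87.5, 75.1, 63.7, 72.3, 29.3 and 50.4 (Ager-null). Donor-derived libraries averaged 15.5 ± 21.1 (SD, n = 12) and recipients 65.1 ± 16.9 (SD, n = 10), with an exact two-sided permutation p = 8.04e-05. Within the 3 ranges of sample numbers the means were 9.92 against 80.9 (2 and 3 libraries), 24.7 against 68.4 (6 and 4) and 4.59 against 44.9 (4 and 3). The library labelled donor into WT replicate 3 lay among the recipients, and directions that rest on the donor into WT group include it. Ptprc, the gene of CD45 (chromosome 1, 138062859 to 138175756), averaged 731 to 985 CPM in the 5 groups.

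**Figure D1:**
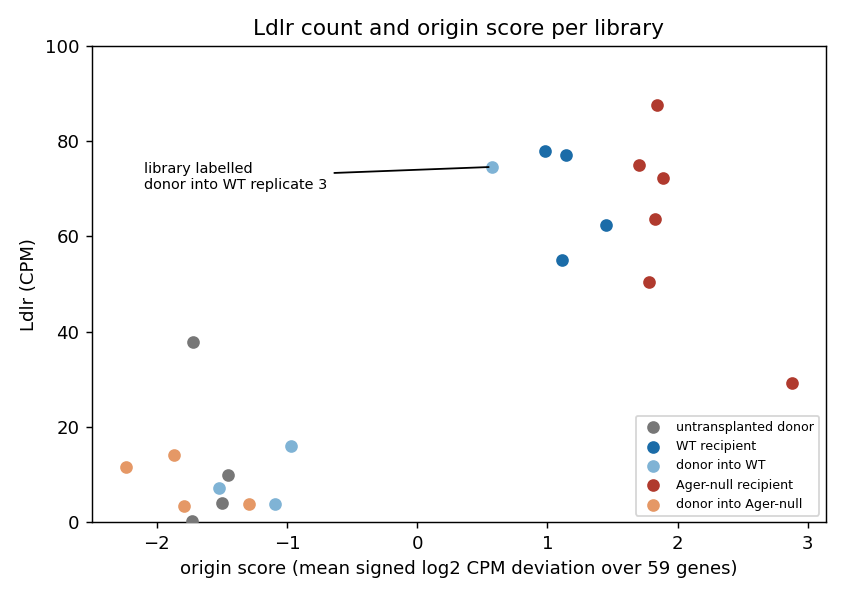
Each point is a library, with its origin score on the x axis and its Ldlr CPM on the y axis, coloured by group. The score is the mean signed log2 CPM deviation over the 59 genes called between Ager-null recipients and donor into Ager-null. The separation of those groups on the x axis follows from that choice of genes. The library labelled donor into WT replicate 3 has a score of 0.577 and an Ldlr level of 74.6 CPM, while other donor-derived libraries score at most -0.969 and recipients 0.983 to 2.88.

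The comparison of Ager-null with WT recipients asks what RAGE does in the macrophages that enter the plaque. Interferon-stimulated genes, the antiviral program driven by type I interferon, were lower in Ager-null recipients: 33 of 35 members had lower estimates, with a median log2 fold change of -0.57 and a mean of -0.75 (adjusted p = 6.28e-18). Oas3, a sensor of double-stranded RNA (chromosome 5, 120753098 to 120777684), was at 51.2 ± 12.3 CPM against 168 ± 69.6, a log2 fold change of -1.71 ± 0.40. Irf7, a transcription factor that amplifies interferon responses (chromosome 7, 141263183 to 141266499), was at 20 ± 8.03 against 54.7 ± 9.25 CPM, -1.45 ± 0.46. Neither gene passed over all genes, while adjusted over the list alone 1 member, Oas3, passed. The list's call held with an estimated correlation (adjusted p = 6.08e-04) and by fry (0.00236). It starts from Irf7 because the study's published title names IRF7, so it is not independent evidence of its direction. The mean score of the list was 4.56 ± 0.226 in Ager-null recipients, highest 4.84, and 5.36 ± 0.194 in WT recipients, lowest 5.1, so 6 of 6 lay below all 4. Within the 3 ranges of sample numbers the difference was -1.2 (1 against 2 libraries), -0.488 (3 against 1) and -0.747 (2 against 1).

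**Figure D2:**
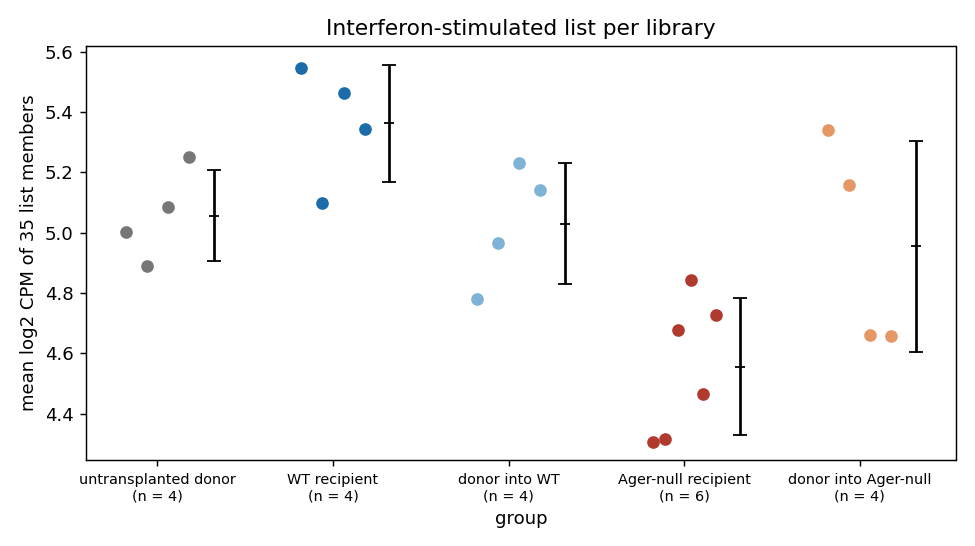
Mean log2 CPM of the 35 interferon-stimulated genes in each library (points) of the 5 groups, with the group mean and SD. Ager-null recipients lie at 4.31 to 4.84 and WT recipients at 5.1 to 5.54, and the other groups have means of 4.96 to 5.06.

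Antigen presentation, proliferation and lipid-handling lists also differed between Ager-null and WT recipients with the preset correlation only. All 10 MHC class II genes had lower estimates (median -1.05, adjusted p = 2.3e-06), such as H2-Eb1 (288 ± 58.1 against 649 ± 325 CPM, -1.17 ± 0.47) and H2-Ab1 (804 ± 275 against 1920 ± 820, -1.25 ± 0.52), with an adjusted p = 0.411 with an estimated correlation. Of the interferon-gamma and guanylate-binding genes 14 of 22 were lower (median -0.33, adjusted p = 3.76e-04, and 0.166 with an estimated correlation). Among them were the GTPases Igtp (13.7 ± 7.31 against 29.9 ± 7.55 CPM) and Gbp7 (45.3 ± 12.9 against 73 ± 10.5). Of the cell cycle genes 24 of 29 were lower (median -0.49, adjusted p = 2.33e-04, and 0.821 with an estimated correlation). Examples were the mitotic kinases Bub1b (-0.81 ± 0.43) and Aurkb (-1.30 ± 0.74). Of the lipid-laden Trem2 macrophage genes 20 of 22 were higher (median 0.32, adjusted p = 0.00329, and 0.821 with an estimated correlation). The fatty acid carrier Fabp5 was at 64 ± 35 against 32.1 ± 16.8 CPM and the elastase Mmp12 at 267 ± 124 against 139 ± 72.7. T cell transcripts moved with these lists: 10 of 12 were lower (median -2.33, adjusted p = 1.3e-04, and 0.333 with an estimated correlation). The summed list was at 44.4 ± 15.6 against 59.5 ± 17.9 CPM. Trbc2, a T cell receptor gene, was at 0.0428 ± 0.0666, near the floor, against 0.96 ± 0.641 CPM. The cell cycle call ended without WT recipient replicate 3 (0.155) or Ager-null recipient replicate 5 (0.0822) and with the sample-number range as a term (0.648). The lipid-laden call ended without Ager-null recipient replicate 3 (0.183), and the T cell call under the stricter filter (0.331).

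No gene differed between Ager-null and WT recipients past the threshold by edgeR (0 genes, 431 at unadjusted p under 0.05, smallest adjusted p = 0.572), while DESeq2 called 48 and limma-voom 4. The smallest p among genes that the naming rule admits fell on Oas3, on Preb, a regulator of transport from the endoplasmic reticulum (84.5 ± 67 against 562 ± 577 CPM), and on Ppfia4, a liprin (0.674 ± 1.11 against 11.5 ± 8.75). The inflammatory cytokine and NF-kB list did not pass (adjusted p = 0.669), but did without Ager-null recipient replicate 5 (0.00255, lower) and, in the other direction, without WT recipient replicate 2 (0.0198). Its member Nlrp3, an inflammasome sensor, was at 681 ± 541 against 1120 ± 1430 CPM. The cholesterol efflux and LXR list (adjusted p = 0.914) and the cholesterol biosynthesis list (0.96) did not pass. The desaturase Scd2 was at 76.8 ± 29 against 37.8 ± 20.6 CPM (1.02 ± 0.41, adjusted p = 1). Among the other lists the adjusted p was 0.762 for RAGE ligand and signalling, 0.777 for alternative activation, 0.854 for the unfolded protein response, 0.562 for migration and chemokine receptor and 0.681 for core macrophage. For markers of other cells it was 0.116 for endothelial, 0.96 for B cell, 0.562 for NK cell, 0.0533 for dendritic cell and 0.562 for adipocyte. These last 10 lists passed in none of the comparisons. Median, mean and test differed in sign for 7 lists here: RAGE ligand and signalling, alternative activation, both cholesterol lists, oxidative phosphorylation, fibroblast and neutrophil.

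Donor into Ager-null against donor into WT asks whether the host's RAGE alters the graft macrophages, which carry Ager themselves. By edgeR 1 gene was higher and 1 lower. Ppp1ca, a catalytic subunit of protein phosphatase 1 (chromosome 19, 4192174 to 4195419), rose from 35.2 ± 8.53 to 136 ± 26.2 CPM, a log2 fold change of 1.95 ± 0.33 (adjusted p = 0.0417). Ppard, the lipid-sensing nuclear receptor PPAR delta (chromosome 17, 28232754 to 28301469), fell from 127 ± 39.2 to 17.1 ± 7.51 CPM, -2.89 ± 0.42 (adjusted p = 0.00718). For each gene 4 of 4 donor into Ager-null libraries lay beyond all 4 of the other group. Chance gives this for 2.86% of unselected genes, but the test selected both, so the separation is no further evidence. Of the 35 interferon-stimulated genes 18 had lower estimates (median -0.03, adjusted p = 0.748), and Irf7 was at 22.3 ± 16.5 against 35.2 ± 13 CPM.

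Both calls depended on 1 library or another in this comparison of grafts. The Ppp1ca call ended without donor into WT replicate 1 (0.214), 2 (0.17) or the library labelled replicate 3 (0.122), and without donor into Ager-null replicate 2 (0.122), 3 (0.2) or 4 (0.139). The Ppard call ended without donor into Ager-null replicate 2 (0.0607) or 4 (0.072). The 2 calls became 3 without donor into WT replicate 4, 1 without donor into WT replicate 1, 2 or the library labelled 3 or donor into Ager-null replicate 3, and 0 without donor into Ager-null replicate 2 or 4. With the sample-number range as a term there were 0 calls. At an unadjusted p under 0.05 there were 1720 genes, while DESeq2 called 235 and limma-voom 0.

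Of the 30 lists 6 passed between the graft groups with the preset correlation, each with an adjusted p = 0.897 with an estimated correlation. Oxidative phosphorylation genes were higher in donor into Ager-null for 20 of 28 (median 0.27, adjusted p = 0.00362; adjusted over the list alone 3 passed, over all genes 0). The cytochrome oxidase subunit genes Cox4i1 (96.2 ± 7.63 against 42.5 ± 13.7 CPM) and Cox6a1 (82.4 ± 15.1 against 37.7 ± 8.03) were among them. Inflammatory cytokine and NF-kB genes were lower for 19 of 24 (median -0.78, adjusted p = 0.00362), with Nlrp3 at 154 ± 78.5 against 624 ± 456 CPM. MHC class II genes were higher for 8 of 10 (adjusted p = 0.0112) and resident-like macrophage genes for 11 of 17 (adjusted p = 0.0202). H2-DMb1 was at 85 ± 50.9 against 39.2 ± 24.6 CPM and the chemokine Pf4 at 247 ± 120 against 120 ± 120. Fibroblast (10 of 10, adjusted p = 0.037) and smooth muscle genes (8 of 10, adjusted p = 0.00666) were lower. The summed fibroblast list was at 3910 ± 7250 against 11600 ± 15100 CPM, with 32190 and 13620 in donor into WT replicates 1 and 2 and 14780 in donor into Ager-null replicate 2. Without those 3 libraries the MHC class II list had an adjusted p = 0.29 in the other direction, the resident-like list 0.534 and the fibroblast list 0.534. Donor into WT then held only replicate 4 and the library labelled replicate 3.

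Each of these 6 calls between the grafts ended with some library left out. Oxidative phosphorylation had an adjusted p = 0.363 without donor into WT replicate 4, and the inflammatory list 0.233 without the library labelled donor into WT replicate 3 and 0.112 without donor into Ager-null replicate 3. MHC class II had 0.607 and 0.0595 without donor into WT replicates 1 and 2, 0.129 without donor into Ager-null replicate 1, and 0.321 with the sample-number range as a term. The resident-like list had 0.236 and 0.703 without donor into WT replicate 1 and the library labelled 3, and 0.113 and 0.224 without donor into Ager-null replicates 1 and 2. Smooth muscle had 0.0716 and 0.0673 without donor into WT replicates 1 and 2, and 0.14 without donor into Ager-null replicate 3. The fibroblast list had 0.5 and 0.494 without donor into WT replicates 1 and 2, 0.0768, 0.51 and 0.122 without donor into Ager-null replicates 1, 3 and 4, and 0.351 with the range as a term.

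Whether the host genotype acts differently on recipient and graft macrophages was tested as an interaction. By edgeR 0 genes passed (1008 at unadjusted p under 0.05, smallest adjusted p = 0.824), DESeq2 called 79 and limma-voom 0. Without donor into WT replicate 4 edgeR called 2. The smallest p fell on Usp36, a nucleolar deubiquitinase (2.63 ± 0.57), Ppp1ca (-1.96 ± 0.44) and Ppard (2.35 ± 0.54). Interferon-stimulated genes had a lower host difference in recipients than in grafts for 30 of 35 (median -0.50, adjusted p = 1.51e-04, and adjusted p = 0.344 with an estimated correlation), with Oas3 at -2.18 ± 0.60 and Irf7 at -0.80 ± 0.69. Adjusted over the list alone 1 passed, over all genes 0, and the list is not independent evidence for the reason given. MHC class II genes were lower for 10 of 10 (median -1.59, adjusted p = 7.78e-07, and adjusted p = 0.621 with an estimated correlation), such as H2-Eb1 at -1.58 ± 0.71, and had 0.117 without the 3 fibroblast-transcript-rich libraries. Smooth muscle genes were higher for 10 of 10 (median 3.11, adjusted p = 0.00275, and 0.876 with an estimated correlation).

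The other 5 lists that passed the interaction test each lost the call with some library left out and had an adjusted p = 0.876 with an estimated correlation. Resident-like genes were lower for 13 of 17 (adjusted p = 0.00669), but 0.0537 without WT recipient replicate 4, 0.0857 and 0.238 without donor into WT replicate 1 and the library labelled 3, 0.0881 without Ager-null recipient replicate 5 and 0.0778 without donor into Ager-null replicate 2. Oxidative phosphorylation was lower for 20 of 28 (0.00676), but 0.349 without donor into WT replicate 4 and 0.0507 without donor into Ager-null replicate 2. Cell cycle was lower for 21 of 29 (0.00676), but 0.132 without WT recipient replicate 3, 0.238 and 0.203 without the library labelled donor into WT replicate 3 and without replicate 4, 0.0549 without the library labelled Ager-null recipient replicate 4, 0.102 without replicate 5, and 0.132 and 0.0568 without donor into Ager-null replicates 2 and 4. Inflammatory genes, with Il6 at 3.12 ± 1.37, were higher for 18 of 24 (0.0225), but 0.0673, 0.153 and 0.104 without WT recipient replicates 1, 3 and 4, 0.38 without the library labelled donor into WT replicate 3, 0.257 without Ager-null recipient replicate 5 and 0.216 without donor into Ager-null replicate 3. Glycolysis, with Eno1 at 1.21 ± 0.49, was higher for 16 of 18 (0.033). It had 0.205, 0.132 and 0.159 without WT recipient replicates 1, 3 and 4, 0.233 and 0.373 without donor into WT replicate 1 and the library labelled 3, 0.0549 and 0.185 without the library labelled Ager-null recipient replicate 4 and without replicate 5, and 0.0514, 0.186 and 0.0568 without donor into Ager-null replicates 2, 3 and 4.

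Donor into WT against untransplanted donor asks how plaque macrophages of the donor change after transplant into a WT host. The matrix and protease list was higher in donor into WT: 14 of 17 members had higher and 3 lower estimates with a median of 1.35 (adjusted p = 9.08e-07), and the call held with an estimated correlation (0.0313) and by fry (0.032). Adjusted over the list alone 7 passed and over all genes 0. Mmp12 (chromosome 9, 7344397 to 7360461) was at 590 ± 422 against 126 ± 99.8 CPM (2.23 ± 0.70), and Adam8, a membrane protease of myeloid cells, at 342 ± 258 against 108 ± 18.5 (1.66 ± 0.52). Fibroblast transcripts moved with the list: 10 of 10 were higher (median 4.68, adjusted p = 9.08e-07, and 0.358 with an estimated correlation). The collagen genes Col1a1 and Col3a1 were at 4870 ± 6180 against 36.7 ± 30.3 CPM and at 3190 ± 4010 against 34.5 ± 27.5. Without the 3 fibroblast-transcript-rich libraries the matrix list had an adjusted p = 0.00187 and the fibroblast list 0.714. In that fit donor into WT held only replicate 4 and the library labelled replicate 3, which had recipient-like Ldlr.

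Other lists differed between donor into WT and untransplanted donor with the preset correlation only, with an adjusted p = 0.358 with an estimated correlation unless another is given. Immediate early genes were lower for 17 of 20 (median -0.64, adjusted p = 5.03e-07; 3 passed adjusted over the list alone, over all genes 0). Among them were the heat shock genes Hspa1a (191 ± 89.8 against 997 ± 320 CPM) and Hspa1b (72.2 ± 46.8 against 375 ± 105). Resident-like genes were lower for 16 of 17 (median -0.77, adjusted p = 9.08e-07), with the transcription factor Maf at 196 ± 157 against 425 ± 120 CPM. Glycolysis genes were higher for 14 of 18 (median 0.75, adjusted p = 3.59e-05; 5 passed adjusted over the list alone, over all genes 0). Pkm was at 249 ± 109 against 113 ± 26.2 CPM and Pgk1 at 12.8 ± 9.57 against 3.9 ± 1.53. Lipid-laden genes were higher for 21 of 22 (median 0.75, adjusted p = 1.05e-04). Spp1, osteopontin, was at 1700 ± 1980 against 241 ± 204 CPM. Cell cycle genes were higher for 24 of 29 (median 0.63, adjusted p = 5.86e-04, and 0.547 with an estimated correlation). MHC class II genes were lower for 8 of 10 (median -0.83, adjusted p = 7.42e-05) and T cell genes for 11 of 12 (median -3.05, adjusted p = 0.00151). The T cell receptor gene Trac was at 1.78 ± 1.66 against 45.8 ± 66.1 CPM. Erythroid genes were lower for 5 of 5 (median -2.08, adjusted p = 0.0256, and 0.507 with an estimated correlation). The interferon-stimulated list did not pass (22 of 35 higher, adjusted p = 0.674).

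Several of these donor into WT calls rested on particular libraries. The lipid-laden list had an adjusted p = 0.104, MHC class II 0.0573 and cell cycle 0.0573 without donor into WT replicate 1, and cell cycle 0.113 without replicate 2. T cell had 0.0778 without untransplanted donor replicate 2, and erythroid 0.0667 without untransplanted donor replicate 4, 0.104 without donor into WT replicate 1 and 0.162 without the library labelled replicate 3. With the sample-number range as a term, MHC class II had 0.0569, cell cycle 0.759 and erythroid 0.254, and without the 3 fibroblast-transcript-rich libraries the lipid-laden list had 0.776, MHC class II 0.986, T cell 0.242 and cell cycle 0.295 in the other direction. By edgeR 0 genes passed (1408 at unadjusted p under 0.05, 171 by DESeq2, 0 by limma-voom) and 1 without donor into WT replicate 4. The smallest p fell on Hspa1a (-2.38 ± 0.44, adjusted p = 0.266), the ribosomal protein gene Rps14 (11.2 ± 7.28 against 67.1 ± 26.8 CPM, adjusted p = 0.327) and Sntb2, a syntrophin (176 ± 98.7 against 38.7 ± 16.2, adjusted p = 0.585).

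Donor into Ager-null against untransplanted donor asks the same of grafts in hosts without RAGE. Immediate early genes were lower for 20 of 20 (median -0.66, adjusted p = 8.61e-08, and 0.336 with an estimated correlation). The phosphatase Dusp1 was at 3830 ± 1160 against 7430 ± 2640 CPM and Junb at 383 ± 139 against 686 ± 91.6. Lipid-laden genes were higher for 21 of 22 (median 1.03, adjusted p = 1.99e-06, and 0.361 with an estimated correlation). Mmp12 was at 549 ± 457 against 126 ± 99.8 CPM and the protease Ctsl at 616 ± 210 against 279 ± 138. Cell cycle genes were higher for 25 of 29 (median 1.02, adjusted p = 3.4e-06, and 0.469 with an estimated correlation). The mitotic kinase gene Cdk1 was at 23.6 ± 17.6 against 3.19 ± 1.09 CPM. Matrix and protease genes were higher for 16 of 17 (median 1.21, adjusted p = 5.22e-04, and 0.208 with an estimated correlation). Ctsk, cathepsin K, was at 16.1 ± 9.13 against 2.5 ± 2.98 CPM. Inflammatory genes were lower for 20 of 24 (median -0.69, adjusted p = 5.22e-04, and 0.469 with an estimated correlation). Cd40 was at 15.5 ± 9.79 against 70.2 ± 49.3 CPM. T cell transcripts were lower for 10 of 12 (adjusted p = 1.99e-06, and 0.252 with an estimated correlation). Adjusted over the list alone 7 passed, over all genes 0. The summed list was at 230 ± 207 CPM in untransplanted donors, and was highest in replicate 2 at 522 CPM. The T cell call ended under the stricter filter (0.23).

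The other 8 lists that passed for donor into Ager-null against untransplanted donor lost the call with some library left out. Glycolysis was higher for 15 of 18 (adjusted p = 0.00532, and 0.469 with an estimated correlation), with 0.0622 without untransplanted donor replicate 3. Oxidative phosphorylation was higher for 21 of 28 (0.0202, and 0.469 with an estimated correlation), with 0.0961 without donor into Ager-null replicate 2. Monocyte-derived genes were higher for 12 of 16 (0.0279, and 0.481 with an estimated correlation). The proteoglycan Vcan was at 125 ± 94.7 against 34.4 ± 18.2 CPM, and the list had 0.643 without untransplanted donor replicate 3 and 0.589 without donor into Ager-null replicate 1. Fibroblast genes were higher for 10 of 10 (0.011, and adjusted p = 0.481 with an estimated correlation), with 0.637 in the other direction without donor into Ager-null replicate 2. Interferon-gamma and guanylate-binding genes were lower for 17 of 22 (0.0244, and 0.455 with an estimated correlation). Gbp7 was at 42.1 ± 17.5 against 89.9 ± 19.8 CPM, and the list had 0.0893 without untransplanted donor replicate 4, 0.196 without donor into Ager-null replicate 3 and 0.0599 with the sample-number range as a term. Resident-like genes were lower for 15 of 17 (0.0356, and adjusted p = 0.594 with an estimated correlation), with 0.135 and 0.0667 without untransplanted donor replicates 3 and 4, 0.746 and 0.0556 without donor into Ager-null replicates 3 and 4, and 0.0655 with the range as a term. Smooth muscle genes were lower for 6 of 10 (0.0244, and adjusted p = 0.481 with an estimated correlation), with 0.0751 without untransplanted donor replicate 3 and 0.133, 0.279 and 0.0928 without donor into Ager-null replicates 1, 3 and 4. The erythroid list passed as lower (0.0279, and 0.469 with an estimated correlation) although its median was 1.19 and its mean 0.64. It had 0.0875 without untransplanted donor replicate 4 and 0.156, 0.196 and 0.191 without donor into Ager-null replicates 2, 3 and 4.

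No gene passed between donor into Ager-null and untransplanted donor by edgeR (1450 at unadjusted p under 0.05, 150 by DESeq2, 0 by limma-voom). The smallest p fell on Lmf2, a lipase maturation factor (75.1 ± 48.9 against 16.6 ± 8.05 CPM), Clptm1l (88.6 ± 37.6 against 25.4 ± 7.5) and Trappc1 (91 ± 57.4 against 24.3 ± 9.95), each with an adjusted p = 0.559. Fdft1, which makes squalene in cholesterol synthesis, was at 32.4 ± 19.7 against 5.94 ± 4.69 CPM (2.45 ± 0.68). Its list did not pass (0.128) but did without untransplanted donor replicate 4 (0.0454). The cholesterol efflux and LXR list (0.0655) passed without untransplanted donor replicate 1 (0.0135) and without donor into Ager-null replicate 1 (0.0101) or 2 (0.0063). The interferon-stimulated list did not pass (0.918), and its median, mean and test differed in sign, as they did for the unfolded protein response.

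The changes of both graft groups against the untransplanted donors shared 0 called genes. Over genes, which are not independent replicates, their fold changes had a correlation of 0.493 and a covariance of 1.66. In 20 simulations of unchanged groups sharing the same 4 controls the correlation averaged 0.504 and the covariance 1.17 (1.12 to 1.23). With the controls split into pairs, in 6 splits, the covariance was 0.476 to 0.737 and the correlation 0.097 to 0.163. The covariance of 1.66 depended on the settings: it was 0.701 with the stricter filter, 0.739 with only the groups compared, 0.705 by limma-voom and 3.05 without untransplanted donor replicate 4.

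Recipient against graft macrophages in WT hosts asks how incoming cells differ from those that stayed. Glycolysis genes were higher in WT recipients for 17 of 18 (median 0.66, adjusted p = 4.07e-06; 2 passed adjusted over the list alone, over all genes 0). Ldha, lactate dehydrogenase, was at 590 ± 294 against 238 ± 75.6 CPM and Pfkl, phosphofructokinase, at 83.7 ± 43 against 24.8 ± 23.6. Neutrophil genes were higher for 12 of 12 (median 2.68, adjusted p = 8.77e-04). Retnlg was at 97.6 ± 112 against 3.36 ± 4.74 CPM, and the summed list reached 6277 CPM in WT recipient replicate 2 (others 338 to 1422). That library also had the highest sum of the glycolysis list (5741 CPM, others 2541 to 2834), and without it the adjusted p was 0.0157 for glycolysis and 0.0388 for neutrophil. Fibroblast (10 of 10, median -5.79, adjusted p = 3e-08; 10 passed adjusted over the list alone, over all genes 0) and smooth muscle genes (10 of 10, median -2.75, adjusted p = 0.00187) were lower. Col1a1 was at 50.8 ± 44.5 against 4870 ± 6180 CPM. Monocyte-derived genes were higher for 11 of 16 (adjusted p = 0.00355). The chemokine receptor Ccr2 was at 475 ± 88.3 against 209 ± 171 CPM and fibronectin, Fn1, at 8300 ± 3270 against 4230 ± 2330. Cell cycle genes were lower for 22 of 29 (adjusted p = 0.0114), with Mki67 at 174 ± 69.1 against 398 ± 259 CPM. Efferocytosis genes were lower for 12 of 18 (adjusted p = 0.0231), with the receptor gene Axl at 142 ± 7.17 against 296 ± 93. For all 7 lists the adjusted p = 0.672 with an estimated correlation. The interferon-stimulated list did not pass (22 of 35 higher, adjusted p = 0.231), nor did MHC class II (0.603).

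No gene passed between WT recipients and donor into WT by edgeR (1719 at unadjusted p under 0.05, 451 by DESeq2, 1 by limma-voom). Without the library labelled donor into WT replicate 3 edgeR called 23 genes, 10 higher and 13 lower, and without replicate 4 it called 1. The smallest p fell on Ppp1ca (107 ± 23.4 against 35.2 ± 8.53 CPM), the cytoskeletal linker Dst (51.4 ± 22.3 against 317 ± 222) and the kinase Cdc42bpa (2.06 ± 1.05 against 37.8 ± 24.5), each with an adjusted p = 0.239. The monocyte-derived list had 0.0733 without WT recipient replicate 2 and 0.0765 and 0.125 without donor into WT replicates 1 and 4. The cell cycle list had 0.382 without WT recipient replicate 2 and 0.202 and 0.342 without donor into WT replicates 1 and 2. Efferocytosis had 0.156 without WT recipient replicate 2 and 0.222 without donor into WT replicate 1. The inflammatory list (0.0813) passed as higher without WT recipient replicate 1 (0.0299), 3 (0.0049) or 4 (0.0192) and without the library labelled donor into WT replicate 3 (0.00383). Without the 3 fibroblast-transcript-rich libraries smooth muscle had 0.555, efferocytosis 0.872 and cell cycle 0.0687 in the other direction.

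Recipients against grafts in Ager-null hosts had the largest count of 7 planned comparisons. With neighbouring sample numbers as a block, a fit of fewer libraries, they did not. By edgeR 10 genes rose and 49 fell in recipients. Genes that rose included Saa3, an acute-phase protein (716 ± 333 against 43.2 ± 42.3 CPM, log2 fold change 4.05 ± 0.84), Vegfa, the angiogenic growth factor (553 ± 74.4 against 46.8 ± 17.5, 3.56 ± 0.68; chromosome 17, 46016993 to 46032377), and Bst1, an ectoenzyme that makes cyclic ADP-ribose (156 ± 59.2 against 28.8 ± 16.1, 2.44 ± 0.37). Hmox1, heme oxygenase (1610 ± 998 against 369 ± 82.9, 2.12 ± 0.42), and Pla2g7, a phospholipase carried by lipoproteins (555 ± 134 against 174 ± 51.5, 1.67 ± 0.26), rose too. Tgm2, a transglutaminase (2.12 ± 0.48), Slc16a6 (1.74 ± 0.38) and the glycolytic enzyme gene Eno1 (1.63 ± 0.35; chromosome 4, 150236708 to 150248879) rose as well.

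The genes that fell in Ager-null recipients against their grafts included several surface molecules. Slamf9, a SLAM family receptor (chromosome 1, 172458569 to 172478421), had the smallest adjusted p (0.00162) and was at 19.5 ± 9.23 against 173 ± 34.7 CPM (-3.14 ± 0.42). Hpgd, which inactivates prostaglandins, was at 7.05 ± 5.39 against 117 ± 31.1 CPM (-4.05 ± 0.61), the adhesion molecule gene Cadm1 at 1.87 ± 2.02 against 69.4 ± 47 (-5.20 ± 0.81), and Lilra5, a leukocyte receptor, at 1.58 ± 1.55 against 85.1 ± 51.7 (-5.76 ± 0.91). The nonclassical class I gene H2-M3 (-3.06 ± 0.49), Cdr2 (-4.75 ± 0.78), the calcineurin-like Chp2 (-7.41 ± 1.26), Igsf9 (-3.85 ± 0.66), Jup, plakoglobin (-2.39 ± 0.41), and the glycosyltransferase Galnt12 (-6.38 ± 1.11) fell as well. Axl, a receptor in the clearance of dead cells, fell from 330 ± 96.2 to 91 ± 35.3 CPM (-1.86 ± 0.33), and Ighm, the IgM heavy chain, from 528 ± 449 to 104 ± 52.4 (-2.34 ± 0.50). The lectin genes Cd209f (0.00663 ± 0.0162 against 31.9 ± 35.7 CPM) and Cd209g (0.0396 ± 0.0368 against 18.1 ± 21.7) also fell, with adjusted p = 0.00918 and 0.0473.

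**Figure D3:**
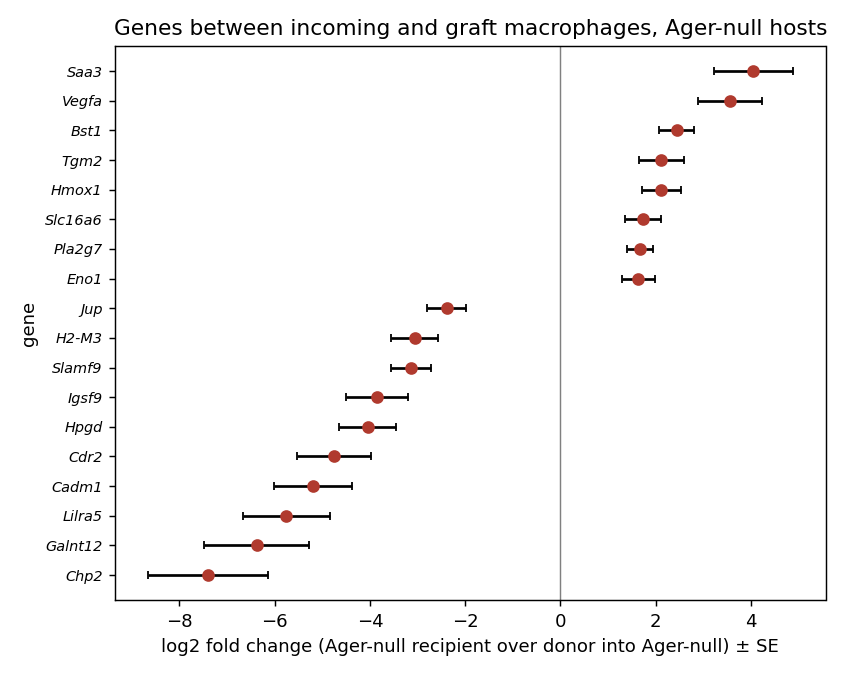
Log2 fold change (x axis, ± SE) of the 18 genes past the threshold that the naming rule took, for Ager-null recipients over donor into Ager-null. The 8 genes that rose lie between 1.63 and 4.05 and the 10 that fell between -7.41 and -2.39.

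For each of these 22 named genes, 6 of 6 Ager-null recipient libraries lay beyond all 4 graft libraries. Chance gives this for 0.952% of unselected genes, but the test selected these, so the separation is no further evidence. Adjusted p-values of the named genes that rose were 0.0048 (Bst1 and Pla2g7), 0.0203 (Vegfa), 0.0241 (Hmox1), 0.041 (Saa3), 0.0414 (Eno1), 0.0443 (Slc16a6) and 0.0495 (Tgm2), and of those that fell at most 0.0473. Of the 22, 13 were called without each of the 10 libraries in turn: Bst1, Pla2g7, Slamf9, Hpgd, Cadm1, Lilra5, H2-M3, Cdr2, Chp2, Igsf9, Jup, Galnt12 and Axl. Vegfa was not called without donor into Ager-null replicate 2, 3 or 4 (highest adjusted p 0.0747), nor Cd209f without Ager-null recipient replicate 1 (0.0714). Each of the 10 libraries, left out, ended 1 or more of the calls of Hmox1 (highest 0.0735), Saa3 (0.101), Eno1 (0.115), Slc16a6 (0.142), Tgm2 (0.138), Ighm (0.164) and Cd209g (0.111).

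The count between Ager-null recipients and their grafts moved with the libraries used and the settings. Of 59 calls there were 25, 37, 34, 28 and 37 without Ager-null recipient replicates 1, 2, 3, 5 and 6, 21 without the library labelled replicate 4, and 37, 35, 41 and 30 without donor into Ager-null replicates 1 to 4. It was 95, including all 59, without the library labelled donor into WT replicate 3, 88 with the sample-number range as a term, 744 by DESeq2 (59 shared), 117 by limma-voom (43 shared) and 38 with only the groups compared, and 2355 genes had an unadjusted p under 0.05. The count fell below each of these with the replicate number as a block. All calls ended with neighbouring sample numbers as a block. Ldlr was at 63 ± 20.6 against 8.22 ± 5.5 CPM (2.94 ± 0.90, adjusted p = 0.158).

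Lists grouped the differences between Ager-null recipients and their grafts, again with the preset correlation. All 18 glycolysis genes were higher (median 1.31, adjusted p = 2.26e-13, and 0.154 with an estimated correlation, 0.0189 by fry). Adjusted over the list alone 12 passed and over all genes 1, Eno1, and Pfkl was at 104 ± 42.5 against 21.1 ± 7.48 CPM. Inflammatory genes were higher for 19 of 24 (median 1.48, adjusted p = 2.31e-06, and 0.377 with an estimated correlation). The prostaglandin synthase Ptgs2 was at 1560 ± 1740 against 176 ± 60.5 CPM and the chemokine Cxcl2 at 5950 ± 5650 against 1120 ± 723. Ager-null recipient replicate 5 had the highest sums of the inflammatory list (57540 CPM, other recipients of the group 6055 to 21540), the glycolysis list (6122, others 2241 to 4535) and neutrophil transcripts (11040, others 334 to 2947). Without it the adjusted p was 4.25e-05 for the inflammatory and 6.2e-12 for the glycolysis list. The neutrophil list did not pass (10 of 12 higher, adjusted p = 0.243). Cell cycle genes were lower for 28 of 29 (median -0.96, adjusted p = 5.09e-10), MHC class II genes for 10 of 10 (median -1.76, adjusted p = 9.1e-08) and interferon-stimulated genes for 27 of 35 (median -0.46, adjusted p = 0.00306), each with an adjusted p = 0.34 with an estimated correlation. H2-Eb1 was at 288 ± 58.1 against 991 ± 317 CPM and Cd74, the invariant chain, at 2270 ± 909 against 7620 ± 3090. Resident-like genes were lower for 14 of 17 (median -1.96, adjusted p = 1.39e-06; 2 passed over all genes), efferocytosis genes for 11 of 18 (median -0.41, adjusted p = 0.0041; 1 passed over all genes, Axl) and fibroblast genes for 10 of 10 (median -4.28, adjusted p = 3.8e-05), each with an adjusted p = 0.459 with an estimated correlation. The interferon call ended without donor into Ager-null replicate 1 (0.14) and the fibroblast call without donor into Ager-null replicate 2 (0.154). The cholesterol efflux and LXR list (0.189) passed as lower without Ager-null recipient replicate 3 (0.0404) or donor into Ager-null replicate 1 (0.0225) or 2 (0.00966). Its transporter gene Abcg1 was at 131 ± 41.9 against 322 ± 213 CPM.

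Across the other comparisons, median, mean and test differed in sign for few lists that had passed. They did so for 4 lists between the grafts (cholesterol biosynthesis, efferocytosis, immediate early and erythroid) and for 7 in the interaction (interferon-gamma and guanylate-binding, cholesterol biosynthesis, efferocytosis, immediate early, core macrophage, dendritic cell and erythroid). They did so for 6 between WT recipients and donor into WT (interferon-gamma and guanylate-binding, MHC class II, alternative activation, unfolded protein response, B cell and erythroid). Between Ager-null recipients and their grafts they did for 7 (interferon-gamma and guanylate-binding, alternative activation, lipid-laden Trem2 macrophage, migration and chemokine receptor, matrix and protease, B cell and erythroid), and for 0 between donor into WT and untransplanted donor. The erythroid list of donor into Ager-null against untransplanted donor was the 1 list of these that had passed.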

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

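The test of the sample-number range, the 3 tests on the library labelled donor into WT replicate 3, the test on fibroblast transcripts and the comparison of origin averaged over hosts were chosen only after the results they bear on were seen.

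The interferon-stimulated list was lower in Ager-null than in WT recipients. With the sample-number range as a term the adjusted p was 1.16e-16, with each library's T cell score as a covariate 2.99e-14 (median -0.553), and with its share of mitochondrial ribosomal RNA 2.38e-17 (median -0.657), so these values argue against each as the whole cause. The real camera p before adjustment was 2.09e-19, the smallest of the other splits gave 4.24e-12, and 1 of 100 splits, the real one, reached the real p. These were 100 of 210 possible splits. The list starts from Irf7, which the study's title names, and the splits do not undo that choice, so they do not exclude chance. Host RAGE genotype, which the design names, stays an open explanation and may act in the macrophages or elsewhere in the host. So does any difference between the groups that the labels leave out, and the Ager counts do not check the genotype.

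The library labelled donor into WT replicate 3 had recipient-like Ldlr and an origin score of 0.577, between the other donor-derived libraries (at most -0.969) and the recipients (at least 0.983). A swap with a WT recipient is excluded, since the lowest WT recipient had 55.1 CPM of Ldlr and the highest of the other donor-derived libraries 37.9. A mixture of recipient and graft cells is a candidate explanation, since the score lay between both. Its Ldlr did not lie between them: at 74.6 CPM it was within the recipients' range of 29.3 to 87.5. Score and Ldlr therefore differ on a mixture. The score lay 0.406 below the lowest recipient, less than the SD of all recipients (0.546), which the rule for this test used. By that rule a recipient library under a wrong label can be neither excluded nor shown. The gap was more than the SD of the 4 WT recipients (0.196), but 4 libraries are too few to decide. The 59 genes of the score were called in Ager-null hosts, so the Ager-null recipients, whose libraries selected these genes, give no fair spread for it, and no biological explanation was tested.

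Between Ager-null recipients and donor into Ager-null 59 genes were called. Alleles that travel with Ager, Ldlr or Ptprc were weighed, since donors and hosts differ at them: 8.47% of the called genes (5 of 59: C4b, Fgd2, H2-M3, Pla2g7 and Vegfa, named after their values were seen) lay within 20 Mb of these genes, against 5.94% of the tested genes placed, so linkage cannot account for most calls. Fibroblast transcripts in donor into Ager-null replicate 2 cannot account for the fold changes. Without that 1 library 98.9% of them (median absolute value) was kept, with 29 of the 59 genes still called. Of 100 splits 1, the real one, gave as many genes (59, highest of the other splits 1), which argues against chance. Host and donor cells also differ in origin, diet history and genotype, which the design names and does not separate, so these stay open.

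Where 0 genes were called, each split has as many by construction, so the splits say nothing about chance. This holds for Ager-null against WT recipients (0 genes, highest other 1, 100 of 100 splits), the interaction (0, highest other 144, 100 of 100), donor into WT (0, highest other 0, 35 of 35) and donor into Ager-null (0, highest other 1, 35 of 35) against untransplanted donor, and WT recipients against donor into WT (0, highest other 1, 35 of 35). For the 2 genes between the graft groups chance cannot be excluded (highest other 76, 4 of 35 splits). The split with 76 genes put donor into WT replicates 1 and 2 together with donor into Ager-null replicates 2 and 4. Such a count, like the 144 in the interaction, points to a structure of the samples that the groups do not give. What that structure is was not shown: the 3 libraries rich in fibroblast transcripts were together in that split, and in others with 37, 17, 1 and 0 genes. For origin averaged over hosts 1 of 100 splits, the real one, gave as many genes (387, highest other 13), which argues against chance.

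Counts of lists called with the preset correlation were matched by other splits in each comparison, so chance cannot be excluded for those counts. The real count, the highest other and the splits as large were 6, 17 and 73 of 100 for Ager-null against WT recipients, 6, 21 and 27 of 35 between the grafts, and 8, 17 and 50 of 100 for the interaction. Against untransplanted donor they were 10, 18 and 13 of 35 for donor into WT and 14, 20 and 4 of 35 for donor into Ager-null. For recipients against grafts they were 7, 18 and 27 of 35 in WT hosts, 8, 15 and 57 of 100 in Ager-null hosts, and 9, 18 and 45 of 100 averaged over hosts.

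By the interaction test the host effect on recipients and on grafts differed for 8 lists, none of which passed with an estimated correlation (smallest adjusted p 0.344). The adjusted p was 1.51e-04 for interferon-stimulated, 7.78e-07 for MHC class II, 0.00669 for resident-like macrophage, 0.00676 for oxidative phosphorylation and 0.00676 for cell cycle, all lower. It was 0.0225 for inflammatory cytokine and NF-kB, 0.033 for glycolysis and 0.00275 for smooth muscle, all higher.

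Single libraries lay far from the rest of their group by Dixon's ratio for 19 of 185 tested sets of values, where chance alone, at about 1 in 20, gives 9.25. The total count was 50 M in WT recipient replicate 4 (others 19.8 to 24). Ager was at 0.238 CPM in untransplanted donor replicate 3 (others 0), 5.34 in the library labelled donor into WT replicate 3 (0 to 0.309) and 6.25 in the library labelled Ager-null recipient replicate 4 (0.166 to 0.795). In untransplanted donors the list score was 5.75 for MHC class II (7.81 to 8.11), 5.3 for RAGE ligand and signalling (6.42 to 6.53) and -0.2 for dendritic cell (2.95 to 3.29) in replicate 3, and 4.75 for oxidative phosphorylation (4.99 to 5.01) in replicate 1. WT recipient replicate 2 scored 2.8 for resident-like macrophage (5.33 to 5.49), 7.29 for glycolysis (6.01 to 6.11), 6.9 for the unfolded protein response (5.62 to 5.78) and 0.617 for NK cell (-1.96 to -1.89). Donor into WT replicate 4 scored 4 for oxidative phosphorylation (4.8 to 4.96) and 3.51 for B cell (-0.85 to -0.439). Ager-null recipient replicate 5 scored 6.09 for efferocytosis (7.13 to 7.59) and replicate 1 scored -0.627 for T cell (-2.05 to -1.7). Donor into Ager-null replicate 2 scored 5.43 for oxidative phosphorylation (5.05 to 5.1), and replicate 1 scored 0.302 for T cell (-1.61 to -1.47) and 4.19 for erythroid (-3.84 to -3.4).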

How the results depend on the processing

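Fits without the library labelled donor into WT replicate 3 and without the 3 fibroblast-transcript-rich graft libraries, the settings of the label tests and of the overlap's covariance, and all settings of the averaged origin comparison were chosen only after the data were seen. Counts below are genes called, and where a count or call changed the cause was not tested.

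The interferon-stimulated list in Ager-null against WT recipients stayed lower and past the threshold under each setting, with adjusted p from 5.69e-19 to 4.72e-12 with the preset correlation, 6.08e-04 with an estimated one and 0.00236 by fry. With a covariate added the adjusted p with an estimated correlation was 0.00319 (T cell score) and 0.00109 (mitochondrial ribosomal RNA). Of the fold changes of named genes under the settings other than single libraries left out, 2414 kept direction and side of the threshold, 142 lost the call, 90 gained it and 12 turned around. For list tests these numbers were 621, 182, 7 and 18. With 1 library left out they were 2852, 192, 18 and 14 for genes and 863, 98, 12 and 21 for lists. Ager had the opposite sign in 32 of 157 settings and comparisons and Ptprc in 18 of 170, neither ever called, so no fold change is given for them. For Ager, depth set the limit in the 7 libraries with a count of 0 (0.0745 to 0.144 CPM), while counts in other libraries reached 192.

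DESeq2 called 48 genes between Ager-null and WT recipients, 235 between the grafts, 79 for the interaction, 171 and 150 for donor into WT and donor into Ager-null against untransplanted donor, 451 and 744 between recipients and grafts in WT and Ager-null hosts, and 1410 averaged over hosts. With limma-voom these were 4 (recipients), 0 (grafts), 1 and 117 (recipients against grafts) and 181 (averaged). With only the groups compared in the fit they were 1 (recipients), 0 (grafts), 38 (Ager-null hosts) and 168 (averaged). RLE size factors gave 1 gene between the grafts. Without a low-count filter there was 1 between the grafts, 1 for donor into WT against untransplanted donor and 228 averaged, and with the sample-number range as a term 0 between the grafts. Without the library labelled donor into WT replicate 3 there were 1 (grafts), 23 (WT hosts), 95 (Ager-null hosts) and 833 (averaged). Without the fibroblast-transcript-rich libraries there were 1 (recipients), 0 (grafts), 1 (WT hosts) and 81 (averaged, 71 shared).

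With the replicate number as a block there was 1 gene between the grafts, 12 in Ager-null hosts (11 shared) and 90 averaged. Irf7 turned to 0.0756 in Ager-null hosts, and Ldlr to 0.172 and Pcsk9 to 0.248 between recipients. The lists of cholesterol biosynthesis (recipients, adjusted p 0.614, and interaction, 0.998) and interferon-stimulated genes (donor into Ager-null against untransplanted donor, 0.903) turned around. With neighbouring sample numbers as a block there were 6 genes in WT hosts, 0 in Ager-null hosts, and Irf7 at 0.0406 there. Deviations of libraries with the same number had correlations of -0.15 to 0.28 over genes, and neighbours -0.046 to 0.23. Of the neighbouring pairs, 1 of 4 in Ager-null hosts and 2 of 3 in WT hosts had a correlation above 0.1. These mixed values do not settle whether the numbers pair the samples. Of the called genes named in Ager-null hosts that held without each library, H2-M3 (adjusted p 0.0615), Cdr2 (0.0711), Chp2 (0.0528), Igsf9 (0.0528), Jup (0.0964) and Galnt12 (0.158) were not called with the replicate number as a block. None was called with neighbouring numbers, where named genes had adjusted p from 0.0523 to 0.296. Averaged over hosts, Arg1 (0.106), Hif1a (0.0626) and Plin2 (0.0834) were not called with the replicate number as a block. Under that block the inflammatory list passed between recipients (0.0155, lower). The calls of efferocytosis in Ager-null hosts (0.123), neutrophil averaged over hosts (0.181), resident-like for donor into Ager-null against untransplanted donor (0.0623), and inflammatory (0.259), glycolysis (0.259), resident-like (0.18) and oxidative phosphorylation (0.117) for the interaction ended.

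Other values turned around, none of them past the threshold in the new direction. For cholesterol biosynthesis between recipients the adjusted p was 0.776 with the stricter filter and 0.937 with the range term, and 0.976 for the interaction with the stricter filter. For interferon-stimulated genes in donor into Ager-null against untransplanted donor it was 0.822 with the range term. For inflammatory genes in donor into WT against untransplanted donor it was 0.982 without a filter, 0.943 with the stricter one, 0.967 by fry and 0.221 without the library labelled donor into WT replicate 3, where Ldlr was at -0.54. By limma-voom Ldlr was at 0.18 and Hba-a2 at -5.16 for donor into Ager-null against untransplanted donor, and Irf7 at 0.42 in Ager-null hosts. Without the fibroblast-transcript-rich libraries, Tpx2 (-0.14) and Cdk1 (-0.54) for donor into WT against untransplanted donor, and Nusap1 (0.27) and Tpm2 (0.99) in WT hosts, turned around. So did the lists of MHC class II between the grafts (0.29), cell cycle (0.295) and cholesterol efflux (0.801) for donor into WT against untransplanted donor, fibroblast for donor into Ager-null against it (0.631), and inflammatory (0.926), cholesterol efflux (0.926) and cell cycle (0.0687) in WT hosts.

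Other list calls changed without turning around. With the stricter filter, calls ended between the grafts for resident-like (0.0524), smooth muscle (0.0993) and fibroblast (0.0626), for glycolysis in the interaction (0.0603), and against untransplanted donor for T cell (0.624) and erythroid (0.347) in donor into WT and for interferon-gamma (0.0553), monocyte-derived (0.0745), smooth muscle (0.154) and erythroid (0.285) in donor into Ager-null. Without a filter the last had 0.123. Without the fibroblast-transcript-rich libraries, calls ended for resident-like in the interaction (0.278), oxidative phosphorylation (0.0874) and erythroid (0.4) in donor into Ager-null against untransplanted donor, fibroblast in Ager-null hosts (0.102), and monocyte-derived (0.0773), cell cycle (0.0679) and neutrophil (0.0612) averaged over hosts. There cholesterol efflux passed between the grafts (0.0165), in the interaction (0.045), for donor into Ager-null against untransplanted donor (0.00735) and in Ager-null hosts (0.00984), and inflammatory for donor into WT against untransplanted donor (0.0246).

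The covariance of the changes of both graft groups against untransplanted donor, 1.66, was 2.39 without a filter, 0.701 with the stricter filter, 0.739 with only the groups compared and 0.705 by limma-voom, and 2.03 to 3.05 with 1 untransplanted donor library left out. No single graft library was left out for it except the library labelled donor into WT replicate 3 (2.01).

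With each library of the groups compared left out in turn the count ran from 0 to 3 between the grafts, 0 to 2 for the interaction, 0 to 1 for donor into WT against untransplanted donor, 0 to 23 in WT hosts, 21 to 41 in Ager-null hosts and 101 to 833 averaged over hosts. The averaged count of 387 moved most without WT recipient replicates 1 (138), 2 (101), 3 (141) and 4 (158), donor into WT replicates 1 (197) and 2 (169), the library labelled donor into WT replicate 3 (833) and donor into Ager-null replicate 2 (152). The exact permutation p of Ager ran from 0.333 to 0.889. Between recipients, Ldlr ran from -0.229 to 0.0343 on the log2 scale, Nlrp3 from -1.23 to 0.75 and Pcsk9 from -4.16 to 0.38. The adjusted p there ran from 0.00255 to 0.902 for the inflammatory list, 0.285 to 0.987 for cholesterol efflux and 0.65 to 0.983 for cholesterol biosynthesis. Between the grafts, Ciita ran from -0.025 to 2.4, the interferon-stimulated list from 0.117 to 0.987 and cholesterol biosynthesis from 0.5 to 0.987, and for the interaction the latter ran from 0.557 to 0.96. For donor into WT against untransplanted donor, Ldlr ran from -0.54 to 2.4, the interferon-stimulated list from 0.408 to 0.946, the inflammatory list from 0.221 to 0.944 and cholesterol efflux from 0.265 to 0.937. For donor into Ager-null against it, Ldlr ran from -1.08 to 0.80, Irf7 from -0.61 to 0.33, Hba-a2 from -8.7 to 1.92, the interferon-stimulated list from 0.136 to 0.993 and the fibroblast list from 8.81e-05 to 0.637. In WT hosts the inflammatory list ran from 0.00383 to 0.953 and cholesterol efflux from 0.256 to 0.905. In Ager-null hosts Irf7 ran from -0.44 to 0.42 and Fcmr from -7.83 to 3, and averaged over hosts Fcmr ran from -6.85 to 1.23.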

Other observations

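The comparison of recipient with graft macrophages averaged over both hosts, and its fits with libraries left out, were chosen only after the data were seen. It asks how incoming macrophages differ from those of the graft whatever the host. By edgeR 107 genes rose and 280 fell in recipients, and 1410 were called by DESeq2 (385 shared) and 181 by limma-voom (138 shared). The count includes the library labelled donor into WT replicate 3 and was 833 without it, with 381 of the 387 among them. It was 81 without the 3 fibroblast-transcript-rich libraries, 138, 101, 141 and 158 without WT recipient replicates 1 to 4, 197 and 169 without donor into WT replicates 1 and 2, and 152 without donor into Ager-null replicate 2.

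Arg1, arginase (chromosome 10, 24915207 to 24927470), rose in recipients by log2 3.41 ± 0.71 (adjusted p = 0.019): it was at 1050 ± 407 CPM in WT and 2060 ± 438 in Ager-null recipients, against 211 ± 268 in donor into WT and 91.6 ± 93.8 in donor into Ager-null. Untransplanted donors had 11 ± 13.5. Chil1, a chitinase-like protein of activated macrophages, rose by 5.29 ± 0.94 (adjusted p = 0.00798), and Hif1a, the oxygen-sensing transcription factor, by 1.26 ± 0.25 (adjusted p = 0.0101). Plin2, which coats lipid droplets, rose by 1.13 ± 0.24 (adjusted p = 0.0159), from 379 ± 86 and 395 ± 194 CPM in the grafts to 786 ± 271 and 916 ± 371 in WT and Ager-null recipients. All 18 glycolysis genes had higher estimates (median 1.04, adjusted p = 2.5e-13, and adjusted p = 0.18 with an estimated correlation, 0.00546 by fry), and 8 passed over all genes, including Ldha (1.31 ± 0.27) and Pfkl (2.03 ± 0.38). Cd81, a tetraspanin, fell (-2.44 ± 0.34, adjusted p = 9.52e-04), from 450 ± 272 and 518 ± 187 CPM in grafts to 89.2 ± 46.6 and 89 ± 45.6, and Axl fell as well (-1.46 ± 0.25). Each gene named in this paragraph was called without each of the 18 libraries in turn. Without the 3 fibroblast-transcript-rich libraries together, Arg1 (2.89, adjusted p = 0.0832), Hif1a (1.17, 0.0837), Plin2 (0.98, 0.107) and Axl (-1.21, 0.0525) kept their direction and were not called. Chil1 was not called by limma-voom (5.23, adjusted p = 0.0895).

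Of the alternative activation list, to which Arg1 belongs, 10 members had higher and 9 lower estimates, and the list did not pass (adjusted p = 0.607), with median, mean and test of different sign. The lists that passed besides glycolysis were cell cycle (adjusted p = 5.06e-08), fibroblast (4.18e-08), inflammatory (6.33e-05), resident-like (5.69e-04), efferocytosis (0.00143), neutrophil (0.00407), MHC class II (0.00793) and monocyte-derived (0.0285). With an estimated correlation the adjusted p was 0.594 for cell cycle, fibroblast and efferocytosis, 0.602 for inflammatory, and 0.689 for the other 4. MHC class II had 0.191 without the library labelled donor into WT replicate 3, 0.145 without replicate 4 and 0.0622 without donor into Ager-null replicate 1. Neutrophil had 0.0519 without Ager-null recipient replicate 5 and resident-like 0.0553 without donor into WT replicate 4. Monocyte-derived had 0.106 without WT recipient replicate 2, 0.116 and 0.17 without donor into WT replicates 1 and 4, 0.0616 without the library labelled Ager-null recipient replicate 4, and 0.0761 and 0.122 without donor into Ager-null replicates 3 and 4. Without the 3 fibroblast-transcript-rich libraries cell cycle had 0.0679, neutrophil 0.0612 and monocyte-derived 0.0773. Ldlr, intact in the hosts, did not pass (2.18 ± 0.62, adjusted p = 0.0623).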
